A study of Bacillus subtilis subsp. subtilis str. 168 and Bacillus subtilis with 4 samples.

How the data were processed

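RNA of 4 cultures of Bacillus subtilis was measured, 2 of the riboflavin producer RH33 and 2 of the wild type 168, on 1 Affymetrix array each. Per the labels' protocols, total RNA was extracted with a RiboPure kit, and 5 µg of it was labelled with the one-cycle protocol. The deposited values are probe set intensities on a linear scale, made with GCOS (Affymetrix GeneChip Operating Software) per the submitters' processing notes. Its version, settings and any scaling between arrays are not given in the sources used here. The medians of the 4 arrays over all 5033 probe sets, controls included, differed by a ratio of 1.175. This was under the limit of 1.2 set before the data were examined, so the deposited values were kept without further scaling. The limit was set on medians only. After trimming 2% of the tested probe sets at each end, the mean signal was 320 and 323 on the 168 arrays. It was 275 on RH33 replicate 1 and 335 on RH33 replicate 2. The labels give the strains as groups and describe the cultures as independent.

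Of 5033 probe sets, 42 controls were left out of the tests, and 4991 were tested: 4345 in genes, 606 between genes and 40 for tRNA. Gene names came from the platform's annotation table for 2942 gene probe sets, each with 1 symbol and 0 with several, and from the name in the array design for the other 1403. Names can therefore be old. Where 85 gene names had several probe sets, the one with the highest mean signal stood for the gene. Neighbouring genes were taken from the RefSeq assembly ASM904v1, used for names and order only, which placed 2753 gene names.

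Values were log2(signal + 8.439), where the added constant is 10% of the median signal over all arrays (84.39), so fold changes are on that scale and understate changes of weak signals. RH33 was compared with 168 by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg over all 4991 probe sets, threshold 0.05), with 2 residual and 6.03 prior degrees of freedom. A 2-fold limit was applied as well. The signal on foreign probe sets (27 per array, against sequences absent from B. subtilis) was taken as background. A gene at or below the highest such signal on both arrays of a strain has only a bound there, given as "at least N-fold", the other strain's level over that background, both without the added constant.

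The statistics, the alternatives except 1, 38 gene lists and the rule for named genes were fixed before the data were examined. The 37 lists with at least 4 measured members were tested with limma's camera on 1 probe set per gene, with a preset correlation of 0.01, and with an estimated correlation and fry beside it. Named genes are all members of the riboflavin, other flavin, purine operon and pentose phosphate lists, the 10 largest rises and the 10 largest falls without overlap between strains, and up to 4 members of every other list with the largest change past the threshold, or 2 where none passed. Genes outside this rule are said to be chosen after their values were seen.

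The limma step was tested on simulated data of the same design over 5 runs of 4991 probe sets. The list step was tested in the first run only, with lists drawn from 4095 genes. Noise was drawn independently for each probe set from the spread model that limma assumes. A smaller share of probe sets was changed than was called in the data, so the rates in the data may differ. Of simulated 2-fold changes 55.9% were recovered, of 4-fold changes 99.1% and of 8-fold changes 100%, with 5.64% of the calls false. The alternatives were no added constant, a higher one (42.2), quantile normalization, median centring, leaving out the 20% dimmest probe sets, no intensity trend, the replicate number as a block, a stricter threshold of 0.01, a fold rule without a test, and leaving out each array in turn. Raising signals to the foreign level was added after seeing the data. Plots and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.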

Results

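Transcript levels of 2 Bacillus subtilis strains were measured on Affymetrix gene expression arrays. RH33 is a strain that produces riboflavin (vitamin B2), and 168 is the laboratory wild type. Each strain was grown in 2 separate cultures in LB with added glucose (1%) and harvested in exponential growth at an optical density (OD600) between 3 and 6, with 1 array per culture. The comparison asks which transcripts differ between the producer and the wild type. The number of arrays, 4, limits the precision of every value. The median signal of the tested probe sets was 81.9 and 87.5 on the 168 arrays and 79.6 and 93.8 on the RH33 arrays. Replicates correlated across probe sets with r = 0.985 in 168 and 0.989 in RH33, and arrays of different strains with r between 0.911 and 0.928. Probe sets for sequences foreign to B. subtilis reached at most 17.3 on any array, and 78.6% and 76.9% of the tested probe sets lay above their own array's highest foreign signal in 168, against 89.6% and 80.3% in RH33. The 3′ over 5′ signal ratio of control genes, often read as a sign of RNA quality, differed between the strains, though not for every control gene. The controls are genes of B. subtilis itself, so RNA quality cannot be told apart here from their own transcription. Over 5 control genes of B. subtilis, the geometric mean of the 3′ over 5′ signal ratio was 0.622 and 0.696 in 168 and 0.939 and 0.915 in RH33, which stands beside every gene group described here. The ratio differed most for the trp control, the weakest of the 5, with 1.12 and 1.08 in 168 and 2.67 and 2.78 in RH33. For the lys control it was 0.888 and 1.08 against 1.54 and 1.25, and for the thr control 0.617 and 0.635 against 0.74 and 0.784. The strains overlapped for the dap control (0.764 and 0.856 against 1.11 and 0.823) and the phe control (0.2 and 0.259 against 0.215 and 0.285).

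RH33 had higher transcript levels than 168 for the genes of riboflavin synthesis and for the roc genes of arginine breakdown. It had lower levels for iron uptake, purine synthesis, many genes of branched-chain and aromatic amino acid synthesis, the prophage PBSX and part of the flagellar and chemotaxis genes. In limma's test, 1122 of 4991 probe sets passed, 598 higher and 524 lower in RH33, and 781 of them changed by at least 2-fold, 391 higher and 390 lower. Without RH33 replicate 1, 743 probe sets passed. Counted by gene name, 970 of 4095 passed, 507 higher and 463 lower. The signals of the strains did not overlap for 65.2% of gene names, where chance gives 33.3%. A permutation test of a single gene cannot go below p = 0.333 with 2 arrays against 2, so the adjusted p-values rest on limma's pooling of the spread across probe sets.

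The riboflavin operon stood far above its wild-type level in RH33. All 5 genes rose (5 also adjusted over the list alone), with a mean log2 fold change of 3.46 and a range from 2.89 to 4.12. The signal of ribG, now called ribD, which encodes the deaminase and reductase of the pathway, was 449.5 ± 88.9 in 168 and 7920.4 ± 595 in RH33 (SD, n = 2 arrays each), a 17.5-fold rise (log2 fold change 4.12 ± 0.23 SE, limma adjusted p = 2.28e-05). The signal of ribA, for the enzyme that opens the ring of GTP, rose from 611 ± 55.5 to 7349 ± 672, or 11.9-fold. Riboflavin synthase (ribB, now called ribE) rose 11.4-fold, lumazine synthase (ribH) 9.07-fold and the last gene, ribT, 7.41-fold. The list passed camera with adjusted p = 1.43e-06, and with adjusted p = 0.586 with an estimated correlation it did not.

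**Figure D1:**
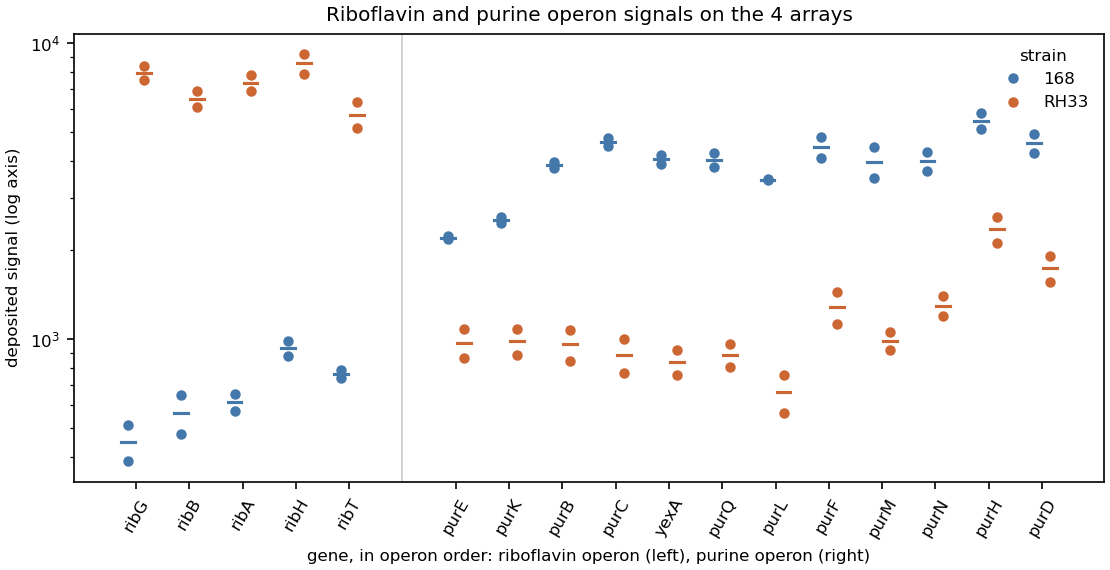
Deposited signal on a log axis for the genes of the riboflavin operon (left) and the purine operon (right), with 1 point per array, blue for 168 and orange for RH33, and a bar at each strain's mean. The mean of ribG was 449.5 in 168 and 7920.4 in RH33, and that of purC 4638 and 884.

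Of 3 other measured flavin genes, 2 rose. The signal of ypaA, for the riboflavin transporter now called ribU, went from 157 ± 1.55 to 698 ± 124 (4.24-fold, limma adjusted p = 0.000495). The signal of ribC, for the enzyme that turns riboflavin into FMN and FAD, went from 871 ± 175 to 2662 ± 552 (3.04-fold, limma adjusted p = 0.00298). A further riboflavin kinase gene, ribR, had signals of 6.01 ± 2.83 in 168 and 9.48 ± 4.28 in RH33 and did not pass (limma adjusted p = 0.414).

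Genes on both sides of the riboflavin operon, chosen after their values were seen, were higher as well. Upstream, ypuD rose from 81.8 ± 60.7 to 479 ± 58.4 (log2 fold change 2.61 ± 0.43 SE, limma adjusted p = 0.00389). Its signals on the 168 arrays were 38.9 and 124.7, and its log2 fold change was 1.87 without 168 replicate 1 and 3.36 without 168 replicate 2. The gene ypuE rose from 113 ± 12.9 to 1343 ± 168 (11.2-fold, limma adjusted p = 3.19e-05), and it is left out of the plot of the region because its position was not matched to the gene order used. Downstream, ypuF rose 3.17-fold, ypuG 6.29-fold and ypuH 4.71-fold. The next genes outward, sipS and ypuI, had log2 fold changes of 0.27 and 0.37 and did not pass (limma adjusted p = 0.401 and 0.279).

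**Figure D2:**
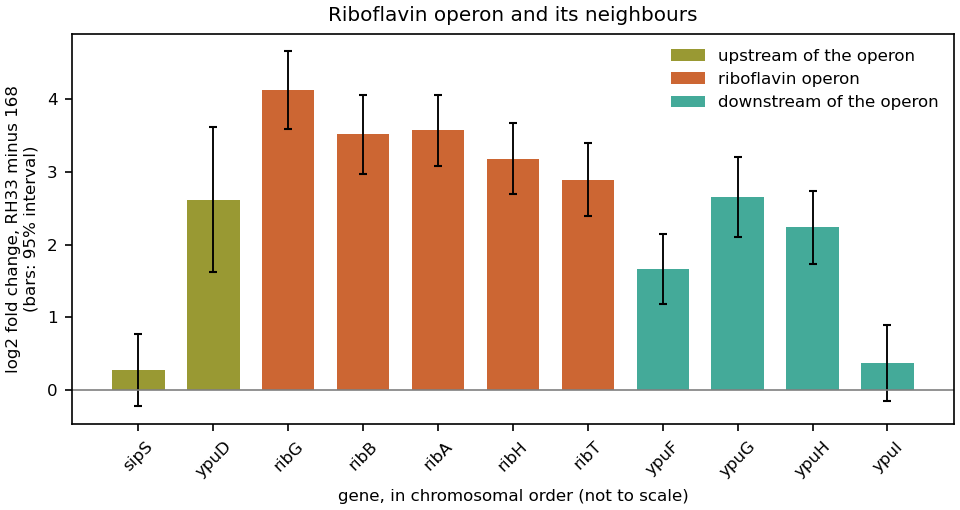
Log2 fold change (RH33 minus 168) of the riboflavin operon and its neighbours in chromosomal order, not to scale, with bars for the estimate and lines for its 95% interval from limma. From ypuD to ypuH, with ypuE not shown, the values lie between 1.66 and 4.12, and sipS and ypuI at the ends lie at 0.27 and 0.37.

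Purine synthesis moved the other way. All 12 genes of the purine operon, which leads to IMP, the precursor of GTP and ATP, fell (12 also adjusted over the list alone), with a mean log2 fold change of -1.82 and a range from -2.39 to -1.18. The signal of purC fell from 4638 ± 217 to 884 ± 162 (limma adjusted p = 0.000233) and that of purL from 3449 ± 17.2 to 661 ± 136. The list passed camera with adjusted p = 3.39e-10, with adjusted p = 0.72 with an estimated correlation. Of 12 further genes of the purine repressor PurR, 8 fell (8 adjusted over the list alone) and 4 did not pass. They included ytiP at -2.00, the xanthine permease gene pbuX at -1.85 and the xanthine phosphoribosyltransferase gene xpt at -1.63 (list adjusted p = 2.04e-05 by camera, and adjusted p = 0.72 with an estimated correlation). In the one-carbon and glycine list, 4 of 11 fell (6 adjusted over the list alone), with serA of serine synthesis at -1.78. That list passed camera with adjusted p = 0.00306, with adjusted p = 0.72 with an estimated correlation, and did not pass without 168 replicate 1 (adjusted p = 0.167). Without 168 replicate 1, 5 of the PurR genes and 1 of the one-carbon genes fell, and without RH33 replicate 1, 2 of the one-carbon genes.

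Pentose phosphate and PRPP genes, which supply the ribose part of the purines, showed no common change (camera adjusted p = 0.392). One of 10 rose (1 adjusted over the list alone), the phosphopentomutase gene drm at 1.94-fold, and its call was lost without 168 replicate 2 (limma adjusted p = 0.114) and without RH33 replicate 2 (0.0557). PRPP synthase (prs) had a log2 fold change of -0.36 (limma adjusted p = 0.271), ribose-5-phosphate isomerase (ywlF) of -0.52 (0.138) and transketolase (tkt) of -0.68 (0.0749). In the pyrimidine operon, pyrR, for its attenuation protein, rose 2.76-fold and the other 9 of 10 genes did not pass (camera adjusted p = 0.586). Without 168 replicate 2, 3 pyrimidine genes rose.

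The 10 largest rises fell mostly into groups with neighbouring names. The signal of yurO was at the foreign level in 168 and 1087 ± 13.3 in RH33, at least 73.9-fold higher by the signals themselves (limma adjusted p = 2.28e-05). The signal of yurP rose from 14.1 ± 0.90, above the foreign level on 1 of 2 arrays, to 1413 ± 83.5 (log2 fold change 5.98, limma adjusted p = 1.2e-05). Both belong to genes for the use of sugar amines. The signal of rocA, for an enzyme of arginine and proline breakdown, rose from 30.9 ± 1.81 to 2439 ± 418, or 61.8-fold. The neighbours yhcE, yhcF, yhcG and yhcH rose 30.7-fold, 22.1-fold, 20.1-fold and 20.7-fold. The gene yvdS rose 21.1-fold and yvdR at least 23.7-fold. A subunit gene of respiratory nitrate reductase, narI, rose from 76.4 ± 40.5 to 1531 ± 50.1, or 19.3-fold.

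The 10 largest falls were led by mcpA, a chemotaxis receptor gene, whose signal went from 1221 ± 309 to 35.8 ± 2.66 (log2 fold change -4.78 ± 0.25 SE, limma adjusted p = 1.96e-05). The flavodoxin genes ykuN and ykuP and their neighbour ykuO changed by -4.57, -4.16 and -4.15. The flagellar stator gene motB changed by -4.49, yfmS by -4.18, the chorismate mutase gene aroH by -4.18, ysbA by -4.16 and yxkC by -4.14. The signal of phrI, a peptide gene of the mobile element ICEBs1, was 166 ± 13.6 in 168 and at the foreign level in RH33, at least 12.3-fold lower.

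Iron uptake genes fell almost throughout. Of 28 genes under the iron repressor Fur, 27 fell (28 adjusted over the list alone), with a median log2 fold change of -2.67. Besides the ykuN group, feuB of siderophore uptake fell from 856 ± 88.0 to 46.6 ± 9.41. The list passed camera with adjusted p = 1.18e-25, with adjusted p = 0.586 with an estimated correlation. Of 17 genes under the peroxide regulator PerR or the envelope stress sigma factor SigW, 10 rose and 2 fell (10 and 2 adjusted over the list alone). The falls were in mrgA and the catalase gene katA, both under PerR, at -2.60 and -1.79, and the rises included racX and pbpE, both under SigW, at 3.54-fold each. This list passed camera as higher with adjusted p = 0.0333, with adjusted p = 0.792 with an estimated correlation. It did not pass with the replicate number as a block (adjusted p = 0.139), by fry (0.103), without 168 replicate 1 (0.115), without 168 replicate 2 (0.284) or without RH33 replicate 2 (0.0863).

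Flagellar and chemotaxis genes split into a part that fell and a part that did not pass. Of 39 measured, 14 fell (14 adjusted over the list alone) and 25 did not pass. The 4 largest falls were in the receptor genes mcpA and mcpB and the stator genes motA and motB, with motA at -3.84 on the log2 scale. Among the others, chosen after their values were seen, flagellin (hag) fell from 5799 ± 115 to 885 ± 194, the filament cap gene fliD by 3.31 and the anti-sigma factor gene flgM by 1.88 on the log2 scale. The gene of the sigma factor for late flagellar genes, sigD, had a log2 fold change of 0.22 and did not pass (limma adjusted p = 0.6). The list passed camera with adjusted p = 1.43e-06, with adjusted p = 0.72 with an estimated correlation. Of 14 biofilm matrix genes, 4 fell (6 adjusted over the list alone), led by cotN, now called tasA, at least 2.62-fold lower. This list passed camera with adjusted p = 0.015, with adjusted p = 0.72 with an estimated correlation. It did not pass with the replicate number as a block (adjusted p = 0.083), with median centring (0.0589), with signals floored at the foreign level (0.119), by fry (0.163), without 168 replicate 1 (0.0761), without 168 replicate 2 (0.226) or without RH33 replicate 2 (0.0918). In the last case 1 biofilm gene fell.

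In amino acid metabolism, many branched-chain and aromatic synthesis genes fell, and the roc genes of arginine breakdown rose. Of 16 CodY targets, 10 fell and 1 rose (10 and 1 adjusted over the list alone), with the branched-chain genes ilvN, ilvB, ywaA and leuB at -2.63, -2.57, -2.48 and -2.25 (camera adjusted p = 0.000741, and adjusted p = 0.72 with an estimated correlation). Of 13 tryptophan and aromatic genes, 7 fell and 1 rose (8 and 1 adjusted over the list alone). Besides aroH, the genes aroB and aroF changed by -3.70 and -3.27, and trpC rose from the foreign level to 42.8 ± 9.22, at least 2.88-fold (camera adjusted p = 0.00427, and adjusted p = 0.72 with an estimated correlation). In the list of amino acid and nucleoside breakdown, 8 of 23 rose (10 adjusted over the list alone). Besides rocA, these included rocB at least 22.8-fold, rocD 5.77-fold and rocE 5.05-fold, all of the arginine pathway (camera adjusted p = 0.000311, and adjusted p = 0.586 with an estimated correlation). The others were drm, named above, and rocC, rocF and dra, chosen after their values were seen. The genes drm and dra act on nucleosides, and their calls depended on single arrays. For drm the limma adjusted p was 0.114 without 168 replicate 2 and 0.0557 without RH33 replicate 2, and for dra it was 0.161 without 168 replicate 2, 0.103 without RH33 replicate 1 and 0.104 without RH33 replicate 2. The hut genes of histidine breakdown did not pass. In histidine synthesis, 3 of 8 fell and 2 rose, with hisZ and hisG at -2.46 and -1.62, and the list did not pass (camera adjusted p = 0.477). The log2 fold change of hisZ was -1.73 without 168 replicate 1 and -3.19 without 168 replicate 2, and that of leuB -1.66 without RH33 replicate 1. The CodY gene that rose, dppC, chosen after its value was seen, lost its call without RH33 replicate 1 (limma adjusted p = 0.0904), with quantile normalization (0.068), with median centring (0.0544) and with signals floored at the foreign level (0.317). Without 168 replicate 1 and without RH33 replicate 1, 3 aromatic genes fell. In histidine synthesis 1 gene rose without 168 replicate 2 and 0 without RH33 replicate 1 or RH33 replicate 2, and 2 CodY genes rose without 168 replicate 2.

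The prophage PBSX had lower transcript levels, and so had part of the mobile element ICEBs1. Most ICEBs1 genes were at or below the highest foreign signal in both strains. Of 29 genes of the defective prophage PBSX, 25 fell (25 adjusted over the list alone), with a median of -1.83, and xkdS fell from 436 ± 24.5 to 77.7 ± 4.80 (camera adjusted p = 2.28e-16, and adjusted p = 0.386 with an estimated correlation). Of 22 genes of the integrative element ICEBs1, 8 fell (10 adjusted over the list alone), with a median of -0.47, and 16 of the 22 were at or below the foreign level on both 168 arrays too, among them rapI and ydcO of the 8, chosen after their values were seen. The call of rapI was lost without 168 replicate 2 (limma adjusted p = 0.0538), and that of ydcO without 168 replicate 1 (0.138), 168 replicate 2 (0.249) or RH33 replicate 1 (0.061). With signals floored at the foreign level, 2 of the 8 still fell, phrI and yddK, and without 168 replicate 2, 5 genes of the element fell. The signal of yddK was 95.9 ± 4.59 in 168 and at the foreign level in RH33, at least 7.12-fold lower. Over all 22 genes the median signal was 7.14 in 168 and 1.28 in RH33. Foreign probe sets had medians of 1.36 and 1.324 on the 168 arrays and 1.249 and 1.665 on the RH33 arrays. The element's median thus differed between the strains below the highest foreign signal. This list passed camera with adjusted p = 7.07e-06, with adjusted p = 0.586 with an estimated correlation, and did not pass with the floor (median -0.08, adjusted p = 0.119). In the SOS response, 3 of 16 rose (4 adjusted over the list alone), with dinG at 3.01-fold, and the list did not pass (camera adjusted p = 0.167). The calls of the other two, dinB and uvrA, were lost without 168 replicate 1 (limma adjusted p = 0.0686 and 0.188), RH33 replicate 1 (0.0685 and 0.0693) or RH33 replicate 2 (0.141 and 0.1).

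Some stress and competence genes rose. Of 27 genes of the general stress sigma factor SigB, 4 rose (2 adjusted over the list alone), with a list median of 0.65 (camera adjusted p = 0.00275, and adjusted p = 0.848 with an estimated correlation). Between the 168 replicates, the median of this list differed by 0.91, and without 168 replicate 1 the median was 0.27 and the list did not pass (adjusted p = 0.498). Of 23 competence genes, 9 rose (11 adjusted over the list alone), among them comEC of DNA uptake at least 2.13-fold (camera adjusted p = 0.00427, and adjusted p = 0.72 with an estimated correlation). The largest rises were in comK at 3.91-fold and smf at 3.47-fold. Their signals on the 2 arrays of 168 were 68.1 and 217 for comK, and 29.9 and 74.4 for smf. The call of comK was lost without RH33 replicate 1 (log2 fold change 2.13) or RH33 replicate 2 (1.8). That of smf was lost without RH33 replicate 2 (1.53). Without 168 replicate 1 the competence list did not pass (adjusted p = 0.0761). These counts depended on single arrays. Of the SigB genes, 1 rose and 1 fell without 168 replicate 1, 12 rose without 168 replicate 2 and 0 without RH33 replicate 2. Of the competence genes, 4 rose without 168 replicate 1, 3 without RH33 replicate 1 and 3 without RH33 replicate 2. Of 12 heat shock genes, 2 rose, with hrcA at 2.45-fold, and of 24 sporulation genes, 3 rose and 4 fell, and neither list passed (camera adjusted p = 0.308 and 0.887). Without 168 replicate 1, 1 heat shock gene rose and 1 sporulation gene fell. Without RH33 replicate 1, 0 sporulation genes fell, and without RH33 replicate 2, 1 rose and 1 fell.

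**Figure D3:**
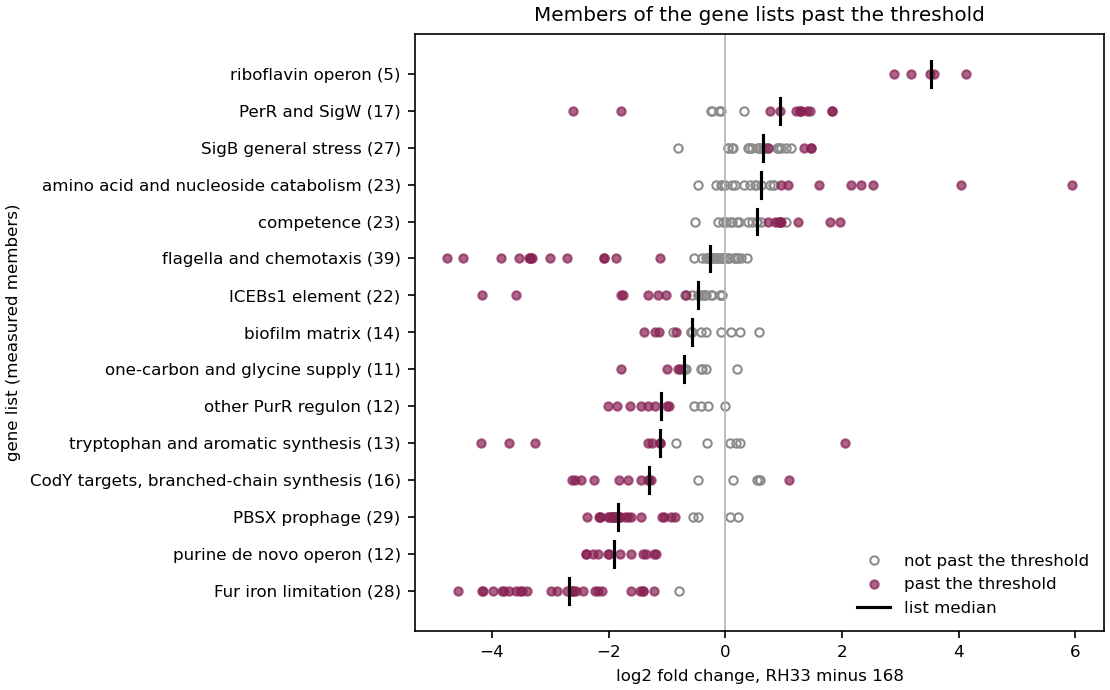
Log2 fold change (RH33 minus 168) of each measured member of the 15 gene lists that passed camera with the preset correlation, with filled points for genes past the limma threshold, open points for the others and a black bar at the list median. Medians run from -2.67 for iron uptake to 3.52 for the riboflavin operon.

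Genes of glycolysis, the ATP synthase, the TCA cycle and ribosomal proteins, like those of some other lists, were called less often than gene names in general (970 of 4095). For the TCA cycle this rests on few genes and depended on single arrays. In glycolysis, 0 of 12 genes passed limma (1 at an unadjusted p under 0.05), and in the ATP synthase 0 of 9 (0 at an unadjusted p under 0.05), and neither list passed (camera adjusted p = 0.455 and 0.772). In the TCA cycle, 2 of 14 fell (4 at an unadjusted p under 0.05), with the fumarase gene citG at -1.36 (camera adjusted p = 0.0668). Of 49 ribosomal protein genes, rpmG rose and rpsD fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.0672). The call of rpmG was lost without 168 replicate 2 (limma adjusted p = 0.0601), RH33 replicate 1 (0.0539) or RH33 replicate 2 (0.132), and that of rpsD without 168 replicate 1 (0.0769), 168 replicate 2 (0.0685) or RH33 replicate 1 (0.174). Without RH33 replicate 2, 3 ribosomal and 5 TCA cycle genes fell, without RH33 replicate 1, 1 TCA cycle gene fell, and without 168 replicate 2, 1 TCA cycle gene rose. Among 47 carbon uptake genes under catabolite repression, 8 rose and 5 fell. The beta-glucoside genes licA and licC rose 4.91-fold and 3.94-fold, and gntR and gntP of gluconate uptake changed by -2.65 and -2.16 (camera adjusted p = 0.174). Of 19 phosphate limitation genes, 6 fell and 1 rose, led by yqgI of the phosphate transport operon at -2.21, with 1 of 2 RH33 arrays above the foreign level (camera adjusted p = 0.0747). The 1 phosphate limitation rise was lost without 168 replicate 1, RH33 replicate 1 or RH33 replicate 2. Of 21 nitrogen limitation genes, 3 rose and 2 fell, with tnrA at 3.48-fold and the glutamate synthase gene gltB at -1.59 (camera adjusted p = 0.308).

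The remaining lists did not pass camera either. Of 21 degradative enzyme genes, 3 rose (5 adjusted over the list alone) and the protease gene epr fell from 680.2 ± 96.3 to 46.0 ± 1.12 (camera adjusted p = 0.178). Of 25 genes for secondary metabolites, 5 rose and 3 fell, with ppsA of plipastatin synthesis at 3.73-fold (0.686). In sulfur and methionine metabolism 4 of 15 fell and 1 rose, with yjcI at -1.58 and the cysteine synthase gene cysK at 2.26-fold (0.266). In the respiratory chain 1 of 16 fell, qoxD at -1.16, and 1 rose (0.935), ctaC, whose call was lost without RH33 replicate 1 (limma adjusted p = 0.0985) or RH33 replicate 2 (0.0559). Among pyruvate and overflow genes, the list median was -0.53, and 8 of 13 had an unadjusted limma p under 0.05. Of the 13, 3 fell (5 adjusted over the list alone), alsD, pta and pdhA, and adhB rose at least 3.06-fold (0.167). These 3 calls were lost without 168 replicate 1 (limma adjusted p = 0.147, 0.188 and 0.261), and also that of pta without RH33 replicate 1 (0.0927) and that of pdhA without 168 replicate 2 (0.143), RH33 replicate 1 (0.0521) or RH33 replicate 2 (0.0546). Without 168 replicate 2, 2 overflow genes rose. Of 12 fatty acid genes 1 rose, yhfB at 4.11-fold (0.201). In 3 lists a single weak call was made. Of 6 gluconeogenesis genes 1 rose, malS (1 higher and 1 lower adjusted over the list alone; 0.932), of 9 arginine synthesis genes 1 fell, argH (0 over the list alone; 0.275), and of 30 genes for other vitamins and cofactors 1 rose, hemB (0 over the list alone; 0.0718). The calls of malS and hemB were lost with any 1 of the 4 arrays left out (limma adjusted p from 0.0802 to 0.227 and from 0.0967 to 0.259), and that of argH without 168 replicate 1 (0.0769), RH33 replicate 1 (0.19) or RH33 replicate 2 (0.0778). For lists given without such a count, the counts adjusted over the list alone were the same. Without RH33 replicate 2, 3 sulfur genes rose and 2 fell, 3 secondary metabolite genes rose and 0 fell, and 1 arginine synthesis gene rose. Without 168 replicate 2, 6 degradative enzyme genes rose, without 168 replicate 1, 3 respiratory genes, and without RH33 replicate 1, 2 fatty acid genes.

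Of the 37 lists tested, 15 passed camera with a preset correlation of 0.01, 5 higher and 10 lower. With a correlation estimated from the 4 arrays, 0 passed camera (2 at an unadjusted p under 0.05), and 6 passed fry: the riboflavin operon, the purine operon, iron uptake, amino acid and nucleoside breakdown, PBSX and ICEBs1. The other 9 lists called by camera did not pass fry, with adjusted p = 0.0589 for flagella and chemotaxis, 0.0707 for CodY, 0.0707 for the further PurR genes and 0.0846 for the aromatic genes. It was 0.103 for PerR and SigW, 0.125 for competence, 0.129 for one-carbon and glycine, 0.163 for biofilm and 0.362 for SigB. On simulated arrays of this design, lists of 12 genes shifted by -1 on the log2 scale were called in 10 of 10 cases with the preset correlation, in 0 of 10 with the estimated one and in 10 of 10 by fry. Lists without a shift were called in 1 of 30, 0 of 30 and 2 of 30. The simulated genes varied independently of each other. In the measured lists that passed, the estimated correlation ran from -0.036 for PBSX to 0.86 for the purine operon. The simulated rates therefore do not show how often a list of correlated genes is called without a shift.

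Intergenic probe sets also differed between the strains. Of 606, 89 passed limma, 62 higher and 27 lower in RH33. The median log2 fold change of the 606 was 0.206, against 0.086 over gene names. Weak signals of genes also tended to be higher in RH33: lists of other genes matched to the 168 signals of ICEBs1 had a median of 0.335. Intergenic probe sets were not matched on signal, so their excess of rises cannot be told apart from this shift. The largest change lay at bases 3574844 to 3575225 in the numbering of the array design, whose genome build is not given in the sources used here, with signals of 4.97 and 23.0 in 168, above the foreign level on 1 of 2 arrays, and a mean of 379 ± 114 in RH33 (log2 fold change 4.21, limma adjusted p = 0.00025). The log2 fold change was 3.59 without 168 replicate 1 and 4.82 without 168 replicate 2. Of 40 tRNA probe sets, 1 passed, as higher.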

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

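A control probe set outside the comparisons gave more signal in RH33 than in 168. The probe set for the 3′ part of the B. subtilis trp control had a mean signal of 62.5 ± 2.7 in RH33 against 36.1 ± 4.23 in 168 (SD, n = 2 arrays each), a ratio of 1.73, above the limit of 1.5. The probe set for the middle part had a ratio of 1.53 and that for the 5′ part of 0.695. Other controls went the other way: the 3 probe sets of the thr control were lower in RH33, with ratios of 0.59 for the 3′ part, 0.495 for the middle and 0.484 for the 5′ part. No explanation was tested.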

How the results depend on the processing

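The floor at the foreign level was chosen after seeing the data, and the other alternatives before. Apart from the fold rule, which was not compared call by call, no setting turned any of the 1122 calls into a call of the other direction, though with the dim filter 1035 of them were tested. With the floor 1114 kept their sign. Leaving out 1 array could not have reversed the calls of the 970 called gene names, since their signals did not overlap between the strains. A threshold of 0.01 gave 593 probe sets, and leaving out 1 array gave 743 to 1301, with the lone array assumed to vary like those of the other strain. Of the 1122, 707 were kept without RH33 replicate 1, which gave the lowest count, and 690 without RH33 replicate 2, the fewest kept. The other settings gave 1094 to 1449. With the replicate number as a block, the count was 1449, of which 1118 were among the 1122. The numbers were not taken as pairs, a choice made before the data were examined, because the labels do not say that equal numbers share a day. Deviations of same-numbered arrays correlated at -0.0231. Of the lists, 15 passed, against 0 with an estimated correlation and 6 by fry, and 11 to 20 with 1 array left out. On simulated arrays, whose genes varied independently, the estimated correlation called 0 of 10 shifted lists and fry 10 of 10. The low count with the estimated correlation therefore says little, and the cause of the lower count by fry was not tested. The count of 15 rests on the preset correlation of 0.01, which treats list members as nearly independent. In the lists that passed, the estimated correlation ran from -0.036 to 0.86. For correlated lists the camera p-values with the preset may therefore be too small, and they do not measure the spread between cultures. A fold rule alone gave 677 probe sets, 597 of them among the 781. The mean log2 fold change of the riboflavin operon ranged from 3.35 to 3.56 and that of the purine operon from -1.97 to -1.67 with 1 array left out. Signals near the foreign level, at most 17.3, limit what weak genes can show.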

Other observations

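The tests in this part were chosen after the results were seen, except that of distance from the replication origin.

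Changed genes often lay close together in the gene order. Among the 2753 placed gene names, there were 22 runs of at least 4 successive genes changed by 2-fold or more in one direction. Of these, 8 were higher and 14 lower, with 135 genes. Genes without a position were skipped, so members of a run need not be direct neighbours. Any of 1000 random gene orders gave at most 3 runs. Such orders break up operons, so the comparison shows only that changed genes cluster. Genes named in this part were chosen after their values were seen. The dlt genes, which add D-alanine to teichoic acids, fell together, from dltA at -1.34 to dltC at -1.93 on the log2 scale, and so did the oligopeptide transporter genes, with oppA at -1.30 and oppB at -1.89. The levan genes levD, levE, levF and levG rose 2.43-fold, 2.57-fold, 2.77-fold and 2.30-fold, the call of levG being lost without RH33 replicate 2 (limma adjusted p = 0.0632). The transition state regulator gene abrB rose from 382 ± 55.7 to 2249 ± 494 (limma adjusted p = 0.000269), and the cell wall protease gene wprA fell from 1786 ± 17.6 to 210.0 ± 31.7 (adjusted p = 5.62e-05).

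Genes next to the riboflavin operon were higher in RH33. In a single copy of the region, transcripts reading on past the end of the operon do not reach the upstream gene ypuD. The log2 change of ypuD was 2.61 (95% interval 1.62 to 3.61, with 1.87 without 168 replicate 1 and 3.36 without 168 replicate 2). This argues against reading on as the cause for ypuD only if RH33 holds a single copy, and the number of copies was not measured. For the downstream genes ypuF, ypuG and ypuH, with a median of 2.24, reading on stays open. Extra copies of a segment with the operon and its neighbours may also contribute, as 9 of 9 genes from ypuD to ypuH, with ypuE left out for want of a matched position, rose 3.17-fold to 17.5-fold. Their log2 changes span 2.46, the ends of the segment were picked from the same values and no DNA was measured, so this hypothesis cannot be decided here.

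All 22 measured genes of the ICEBs1 list, or 100%, were at or below the foreign level on both RH33 arrays, against 5.55% of other genes and 0 of 6 flanking genes. The gene ydcM was not in the list and counts among the other genes. It too was at or below that level on both RH33 arrays, with signals of 10.5 and 35.1 in 168. Weaker low signals on the RH33 arrays are argued against for the 5 genes that were above the foreign level on both 168 arrays. Of 10000 lists of other such genes matched on 168 signal, 0% had 5 genes at or below that level on both RH33 arrays, and the highest count was 2. For the other 17 genes this explanation stays open, since 94.1% of them were at that level on both 168 arrays too. That RH33 lacks the element is a hypothesis that stays open for the same reason, and no DNA was measured.

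The nitrate respiration genes rose as a block, 8 of 8 with a median of 2.85, among them narH at 13.6-fold and narJ at 15.8-fold. The call of fnr was lost without 168 replicate 2 (limma adjusted p = 0.057), RH33 replicate 1 (0.05) or RH33 replicate 2 (0.0832), and that of narK without RH33 replicate 2 (0.055), whose log2 change of 1.95 was 1.28 without 168 replicate 2 and 2.61 without 168 replicate 1. Less oxygen in the RH33 cultures may be a cause, although the median of 12 other genes known to be induced by low oxygen was 0.141, with 0 risen and 1 fallen (limma), below a bound of 0.713 set from the nar median by more than their SD of 0.518. Without 168 replicate 1, cydD of these 12 rose (log2 change 1.73, adjusted p = 0.0012) and the fallen one, alsD, did not pass (0.147); in that case (0.376 against 0.789, SD 0.649) and without RH33 replicate 1 (0.243 against 0.726, SD 0.518) the median still lay below the bound, but by less than the SD. All 12 and all 8 were higher in 168 replicate 1 than in 168 replicate 2, so the explanation cannot be excluded.

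A different gene dosage between replication origin and terminus, a hypothesis set before the data were examined, predicts a trend of log2 changes with distance from the origin. Across 2753 genes, which are not independent replicates, Spearman's correlation was 0.0014 and Pearson's -0.0051 (permutation p = 0.943), which argues against it.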
